A study of Mus musculus with 12 samples.

How the data were processed

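Small RNA libraries were made from 4 mouse cell types, each in 3 genotypes, with 1 library per combination (12 libraries). Per the labels, RNA of 19 to 30 nt was cloned by a route that takes up only molecules with a 5′ phosphate and a 3′ hydroxyl, the ends left by RNase III enzymes. The genotypes were control, Drosha-deficient and Dicer-deficient, and groups were taken from the sample titles. The aligner, the read counting, the miRBase release and the genome build were not given in the sources used here.

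The deposited miRNA values were treated as scores: whole numbers that sum to about 1000000 in most libraries, per-million values rounded by the authors as far as the values and most file headers show. Deposited totals ran from 893850 in the CD4 Dicer library to 1027032 in the Treg Drosha library. For DN3 and Treg cells each entry was 1 distinct sequence with its miRNA and its part of the hairpin (guide, passenger, pre or loop), and no entry lay below 10. For CD4 cells and embryonic fibroblasts each entry was 1 mature miRNA. A miRNA missing from a list was taken as below that library's floor, not as 0. The floor for DN3 and Treg libraries applies to each sequence, so a summed miRNA below it can exceed 10. Files of the 2 formats may have been made by different steps, so levels were not tested between cell types.

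Depth was estimated where the values allowed it. In the CD4 and fibroblast lists the low values were multiples of a fixed step, within a tolerance of 0.6, which gave the value of 1 read. The implied totals were about 100000 reads for CD4 control, 7600 for CD4 Drosha and 6200 for CD4 Dicer. For the fibroblasts they were about 274800 (control), 77400 (Drosha) and 270000 (Dicer). The share of low values that came out whole was 100% in 4 of these libraries, 82.2% in fibroblast Dicer and 68.0% in CD4 Dicer. In CD4 Dicer, 2 steps worth 6100 and 6200 reads for the first and second part of the list made 75 of 75 low values whole. The step of 10 in CD4 control could also come from rounding. The depth of the DN3 and Treg libraries is unknown. Intervals from implied reads are 95% exact (Clopper-Pearson) intervals, cover counting error only and are estimates. The CD4 deletion libraries list no miRNA below 4 reads.

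Guide and passenger values were summed per miRNA name after removal of the species prefix and of the locus copy number, which gave 430 names, 51 of them listed in all 12 libraries. Of these names, 192 occurred only in the CD4 and fibroblast lists and 35 only in the DN3 and Treg lists. Read counts had been assumed when the tests were fixed. Because the files hold normalised values, the fallback fixed at that time was used: limma on log2(value + 1), with cell type as a block and genotype as the factor, over all 12 libraries. Fold changes are on that scale. The planned minimum of 10 in at least 4 libraries could not be applied to lists with floors. A cell type was used for a miRNA only where all 3 of its libraries listed it at 10 or more, and at least 2 such cell types were required (185 miRNAs, of which 76 had 2 cell types, 58 had 3 and 51 had 4). This rule was set after the file format was known and before any comparison was computed. It leaves out miRNAs that fell below a floor. The replicates of this fit are cell types, so its p-values set the mean genotype effect against its differences between cell types. With 1 library per combination, those differences cannot be separated from the noise of single libraries. Benjamini-Hochberg adjustment and a threshold of 0.05 were used. Each value is relative to the other miRNAs of its library, so a fall of all miRNAs together cannot be seen.

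The fit was tested on simulated data for the Dicer to Drosha comparison, with 30 of 185 miRNAs changed in 20 runs. It recovered 1.17% of changes of 1 log2 unit, 35.0% of 2 units and 83.3% of 3 units, with 1.00 false call per run at 3 units. The simulated spread was held between set limits, the noise was independent between miRNAs, and each change was the same in every cell type. These settings are simpler than the data, so the recovery there may be lower. Preset miRNA lists were tested with limma's camera at a correlation of 0.01 for lists with at least 3 tested members, which gave 30 list tests adjusted together. Names were matched without arm and copy number, and miR-1937a, miR-1937b and miR-1937c were taken as miR-1937.

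Within a cell type there was 1 library per genotype, so no test was run and no difference has a replicate check. The log2 ratio used a pseudocount of 0.5 and was set against the median miRNA among those listed in both libraries with a summed value of at least 50. List medians were placed among 10000 random lists of the same size drawn from the 20 miRNAs nearest in expression. The named miRNAs were the 10 most abundant per control library and the 5 highest and 5 lowest ratios per comparison within a cell type. Across cell types the 5 with the lowest p were named. All mirtron or short hairpin entries, entries derived from other non-coding RNA and the slicer-processed entry with a summed value of at least 20 were followed, and up to 4 members of other lists. Lists, rule and tests were fixed before the data were examined.

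For DN3 control, a deposited list gave distinct small RNA sequences within genes with symbol, strand and position. Its position columns were used as other information, and it gives no abundance. Its build was not given in the sources used here. Its highest position on chromosome 1, 196957914, lies beyond the last feature annotated there in GRCm38 (195323493), so no GRCm38 coordinate was set beside it. Starts counted from 0 and are given from 1. The sequences were also searched, as exact matches, in the 2201 miRNA transcripts named in GENCODE M21. Positions given for miRNA genes are from that annotation (GRCm38).

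Alternatives were median-of-ratios scaling, shares of all listed values, no filter, a minimum of 50, sums over arms, only the 2 genotypes compared, leaving out each cell type, other pseudocounts (5 within a cell type and 10 in the fit), a minimum of 200, floors in place of missing values and only miRNAs listed in all 12 libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. Of the genes with most small RNA sequences in DN3 control cells, 1 is not reported here.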

Results

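Small RNAs were profiled in DN3 thymocytes (immature T cell precursors that carry neither CD4 nor CD8), CD4+CD25+ regulatory T cells (Treg), CD4+ T cells and embryonic fibroblasts (MEF) of mice. Each cell type was taken as control, with a deleted Drosha gene or with a deleted Dicer gene. Drosha releases the miRNA hairpin from the primary transcript in the nucleus, and Dicer cuts the hairpin into the mature duplex. The deletions were made with Lck-cre in DN3 cells, CD4-cre in Treg and CD4 cells, and an inducible Cre in E14.5 embryonic fibroblasts. Neither Drosha nor Dicer mRNA was measured by these lists, so the extent of the deletions is not known from them. The lists held 208, 188 and 203 miRNAs for DN3 control, Drosha and Dicer, 197, 208 and 192 for Treg, 272, 85 and 97 for CD4 and 312, 278 and 301 for MEF. The CD4 Drosha and CD4 Dicer libraries were shallow, at about 7600 and 6200 reads, and their lowest values were 526 and 645.

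The control libraries differed in their main miRNAs. miR-16 (13.8% of the listed values), miR-181a (10.01%) and miR-20a (9.25%), a member of the miR-17~92 cluster, led in DN3 cells. In Treg cells miR-21 (17.2%), miR-16 (11.5%), miR-142-5p (9.50%), miR-29b (9.30%) and miR-29a (8.78%) led. CD4 control was led by miR-22 at 15.2% (95% exact interval 15.1 to 15.5%), miR-423-5p at 10.2% and miR-93 at 5.77%. In MEF control miR-22 took 55.8% (55.7 to 56.0%) and miR-125b-5p 11.5%. The remaining miRNAs among the 10 most abundant were miR-21, let-7f, miR-15b, let-7a, miR-128, let-7g and miR-142-5p in DN3, and let-7g, miR-15b, let-7f, miR-142-3p and let-7a in Treg. In CD4 they were miR-142-3p, miR-423-3p, let-7i, miR-296-3p, miR-210, miR-191 and miR-689, and in MEF miR-127, let-7i, miR-143, miR-541, miR-320, miR-125a-5p, miR-31 and miR-99b.

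Lists of cell type miRNAs separated the controls. T lymphocyte miRNAs took 47.4% in DN3, 72.6% in Treg, 16.9% in CD4 and 3.04% in MEF. Fibroblast and mesenchymal miRNAs took 72.7% in MEF, 15.5% in CD4, 1.77% in Treg and 0.633% in DN3, and in CD4 this was almost all miR-22, since the share was 0.291% without it. The miR-17~92 cluster and its paralogs took 19.7% in DN3 and 3.96% in Treg. miRNAs of the imprinted Dlk1-Dio3 region took 6.41% in MEF and were not listed in DN3 or Treg. Erythroid miRNAs took 0.559% in DN3 and 0.120% in Treg, and epithelial miRNAs were at or below 0.0489% in each control. The DN3 and Treg lists differ in format from the CD4 and MEF lists, and these shares have no replicate check.

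The comparison of Drosha-deficient with control cells asks which small RNAs remain when the nuclear step is removed. miR-320 had a higher value in all 4 Drosha libraries, by 2.44 log2 units in DN3, 1.86 in Treg, 2.31 in CD4 and 4.04 in MEF, and its fitted change was 2.66 ± 0.55 (SE, 4 cell types). miR-484 was also higher in 4 of 4, with a fitted change of 2.58 ± 0.81, but by only 0.32 in DN3. Values below control were seen in 4 of 4 cell types for miR-7a (-3.31 ± 0.88), miR-378 (-1.64 ± 0.41) and miR-671-5p (-1.80 ± 0.52, but -0.10 in DN3), and for miR-342-5p (-1.90 ± 0.42), measured in 3 cell types. In DN3 miR-342-5p was not listed in control and stood at 25 in Drosha, and with floors in place of missing values it was at -1.11. With median-of-ratios scaling miR-378 was at -0.99, miR-671-5p at -1.15 and miR-342-5p at -1.08, and without MEF miR-7a was at -2.37. The Drosha values of miR-7a rest on about 4 reads in CD4 and 3 in MEF. In limma's test across cell types none of the 185 miRNAs passed: 0 calls, with 37 at an unadjusted p under 0.05 and an adjusted p of 0.17 for miR-320. Among the 51 miRNAs listed in all 12 libraries, an alternative added after the data were seen, 7 passed: miR-320, miR-484 and miR-720 higher, miR-7a, miR-378, miR-671-5p and miR-423-3p lower. A miRNA of this set had to reach the floors of CD4 Drosha (526) and CD4 Dicer (645). miR-720 stood at 30 in CD4 control, or about 3 reads, so the set could hold it only with a rise there. In DN3 miR-720 was lower in Drosha (495) than in control (599).

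The median miRNA of this comparison lay at -0.52 log2, or -0.21 with median-of-ratios scaling. Entries derived from other non-coding RNA, such as fragments of tRNA and rRNA annotated as miRNAs, had a median of 2.89 over 9 tested members, none of which passed alone. As a list they were higher by camera (adjusted p = 3.2e-09), but the adjusted p was 0.17 with an estimated correlation. Only miR-720 and miR-805 of these members were also fitted in DN3 and Treg, and the others rest on CD4 and MEF. A member low in CD4 control entered the CD4 fit only if it reached the floors of CD4 Drosha (526) and CD4 Dicer (645). The list test cannot part this from an effect on the list. For the mirtron or short hairpin list, whose hairpins form by splicing or directly by transcription, the 2 tested members, miR-320 and miR-484, both passed when adjusted over the list alone. The miR-17~92 list had a median of -0.79 (18 members, adjusted p = 0.17). The T lymphocyte, let-7, miR-30, fibroblast, erythroid, myeloid, activated T cell and Treg lists had no member past the test, with list adjusted p from 0.58 to 0.98. The endothelial, epithelial, slicer, other tissue and Dlk1-Dio3 lists had fewer than 3 tested members in each comparison, and none of these passed.

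Within single cell types the Drosha libraries departed from control to different degrees. Ratios at least 1 log2 unit from the median miRNA were found for 65 of 168 miRNAs in DN3, 55 of 171 in Treg, 53 of 80 in CD4 and 83 of 227 in MEF. The CD4 Drosha library, at about 7600 reads, lists nothing below 526, against 20 in CD4 control. A miRNA below 526 in control is compared there only if it was higher in Drosha, so the CD4 count is not comparable with the others. In DN3 the 5 highest were miR-342-3p (3.45 relative to the median miRNA), miR-320 (2.82), miR-351, miR-31 and miR-503, and the 5 lowest were miR-466b-3p (-3.56), miR-149 (-2.78), miR-32, miR-374 and miR-7a*. In Treg the highest were miR-223 (4.72), a myeloid miRNA, miR-484 (4.26), miR-138, miR-183 and miR-181a*, and the lowest miR-874 (-2.42), miR-378 (-1.86), miR-378*, miR-297c and miR-219. In CD4 the highest were miR-1937b (9.09), miR-677 (7.36), miR-1195, miR-720 and miR-1959, and the lowest miR-296-3p (-3.60), miR-7a (-3.34), miR-298, miR-423-3p and miR-185. The CD4 control values of miR-1937b, miR-677 and miR-720 were only 40, 40 and 30, at about 10 per read. The CD4 Drosha value of miR-7a was 526, or about 4 reads, and that of miR-185 was 658. In MEF the highest were miR-689 (7.15), miR-320 (4.99), miR-1937b, miR-1839-5p and miR-1937a, and the lowest miR-7a (-5.20), miR-27a* (-4.36), miR-665, miR-149 and miR-92a, whose Drosha values rest on about 3, 2, 3, 4 and 2 reads. Measured against the library total in place of the median miRNA, 24 MEF miRNAs were higher and 104 lower, against 47 and 36.

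**Figure D1:**
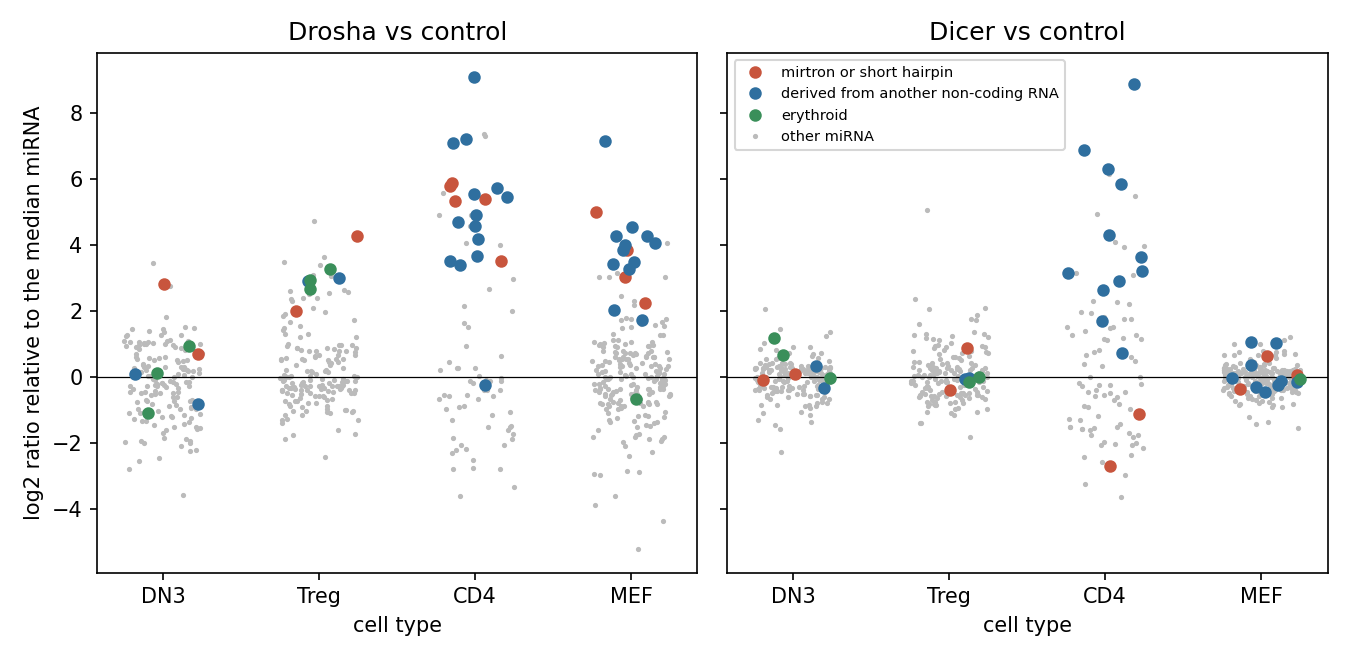
Each point is 1 miRNA listed in both libraries of a cell type; the vertical axis is its log2 ratio (deletion over control) relative to the median miRNA, and the horizontal axis is the cell type. Colours mark 3 preset lists. The entries derived from other non-coding RNA reach 9.09 in CD4, over about 4 control reads, and 7.15 in MEF in the Drosha comparison.

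Groups of entries stood above control together in some Drosha libraries. In the Treg Drosha library the erythroid miRNAs miR-451 (1102 in control, 7748 in Drosha), miR-144 (73 and 648) and miR-486 (23 and 137) were higher, with their list median at percentile 99.1 of matched random lists. In the same library the tRNA-related miR-720 (275 and 2011), miR-805 (51 and 349) and the endothelial miR-126-3p (34 and 181) were also higher, as were miR-181a (13227 and 59531) and miR-128 (935 and 4471). The fibroblast and activated T cell lists lay at percentiles 97.6 and 98.3 there. In DN3 miR-451 was 5126 in control and 4268 in Drosha, and miR-720 was 599 and 495. In CD4, miR-689 was 30690 in control and 344342 in Drosha, or 37.8% of that library, while in MEF it was 84 and 6240. The mirtron miR-877 was not listed in DN3 control and stood at 109 in DN3 Drosha, and in Treg it was not listed in control and stood at 428 in Drosha. miR-877* was 250 in control and 4342 in Drosha in CD4, and 33 and 142 in MEF. miR-702 was 50 and 921 in CD4, and 22 and 168 in MEF.

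The comparison of Dicer-deficient with control cells asks which small RNAs depend on the cytoplasmic step. Relative to the other miRNAs of a library, the Dicer libraries of DN3, Treg and MEF cells lay near their controls. A fall of all miRNAs together would not be seen in these values, and the extent of the deletions is not known from them. Only 14 of 183 miRNAs in DN3, 25 of 166 in Treg and 10 of 235 in MEF differed by 1 log2 unit or more from the median miRNA, against 67 of 94 in CD4. The correlation of log2 values across miRNAs, which are not replicates, was 0.986 in MEF, 0.984 in DN3, 0.965 in Treg and 0.538 in CD4. The CD4 Dicer library, at about 6200 reads, lists nothing below 645, against 20 in CD4 control. A miRNA below 645 in control is compared there only if it was higher in Dicer. The CD4 count and correlation are therefore not comparable with those of the other cell types. limma's test across cell types gave 0 calls among 185, with 4 at an unadjusted p under 0.05. The lowest p belonged to miR-1959 (3.55 ± 1.29), miR-690 (3.31 ± 1.22), miR-709 (2.35 ± 0.87), miR-223 (3.49 ± 1.30) and miR-362-3p (1.23 ± 0.53), each measured in 2 cell types, with an adjusted p of 0.99. The value of miR-223 was 1.77 without the filter, when MEF, where it went the other way, was included.

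In this comparison the median miRNA was at -0.09 log2, and at 0.24 with median-of-ratios scaling. The entries derived from other non-coding RNA had a median of 1.69 and a camera adjusted p of 9.5e-08, which became an adjusted p of 0.21 with an estimated correlation. The shallow CD4 library and MEF differed here: miR-1937b was 40 in control and 18226 in Dicer in CD4, but 215 and 174 in MEF. Here too, a member low in CD4 control entered the CD4 fit only if it reached the floors of the CD4 deletion libraries. The miR-17~92 list, 18 members with a median of -0.45 and none past the test alone, was lower by camera (adjusted p = 0.021), and the adjusted p was 0.79 with an estimated correlation. The mirtron or short hairpin list had a median of -0.54 over 2 members, and neither passed. For the 8 remaining lists with at least 3 tested members the adjusted p ran from 0.38 to 0.97.

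Among single cell types, miR-223 was the highest in Treg Dicer (24 in control, 746 in Dicer) and in DN3 Dicer (28 and 121), and the lowest in MEF Dicer (47 and 14). The next highest were miR-503, miR-30a, miR-138 and miR-146b in Treg, and miR-362-3p, miR-342-3p, miR-328 and miR-486 in DN3. The lowest were miR-874, miR-181d, miR-31, miR-378 and miR-219 in Treg, and miR-421, miR-18b, miR-449a, miR-7a and miR-669c in DN3. In MEF the highest were miR-369-5p (1.23 relative to the median miRNA), miR-133a, miR-1959, miR-690 and miR-155, and the lowest after miR-223 were miR-23a, miR-142-3p, miR-30c and miR-675-3p. In CD4 the highest were miR-1937b (8.88), miR-720, miR-1959, miR-677 and miR-690, and the lowest miR-298 (-3.63), miR-296-3p, miR-181c, miR-320 and miR-423-3p. The miR-1937b and miR-720 ratios rest on about 4 and 3 reads in CD4 control. Among matched random lists, the list medians below percentile 1 or above 99 were those of the let-7 list in DN3 (0.105, median -0.51), the T lymphocyte list in DN3 (99.3), the Treg and activated T cell lists in Treg (99.8 and 99.3) and the list of entries from other non-coding RNA in CD4 (99.9). The let-7 list lay at 78.1 in Treg, 63.8 in CD4 and 97.7 in MEF.

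The direct comparison of Dicer-deficient with Drosha-deficient cells asks which small RNAs may need only 1 of the enzymes. A difference alone does not show this, since the values are relative and the extent of the deletions is not known. miR-320 was lower in Dicer than in Drosha libraries in 4 of 4 cell types, by 5.69-fold in DN3 (6193 in Drosha, 1087 in Dicer), 5.23-fold in Treg (2950 and 564), 33.8-fold in CD4 (141711 and 4194) and 17.8-fold in MEF (193941 and 10900). It was the only miRNA past the threshold in limma's test, with a log2 change of -3.53 ± 0.55 and an adjusted p of 0.022, and 21 miRNAs had an unadjusted p under 0.05. The CD4 value rests on about 26 reads in the Dicer library, for a ratio of 0.0296 (95% interval 0.0192 to 0.0436). Without the CD4 libraries the adjusted p was 0.064 (-3.02 ± 0.48), without MEF 0.077 (-3.32 ± 0.62), and with floors in place of missing values also 0.077. The miR-320 hairpin gene lies at chromosome 14, 70443510 to 70443591 (GRCm38), outside other annotated genes of the classes searched.

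**Figure D2:**
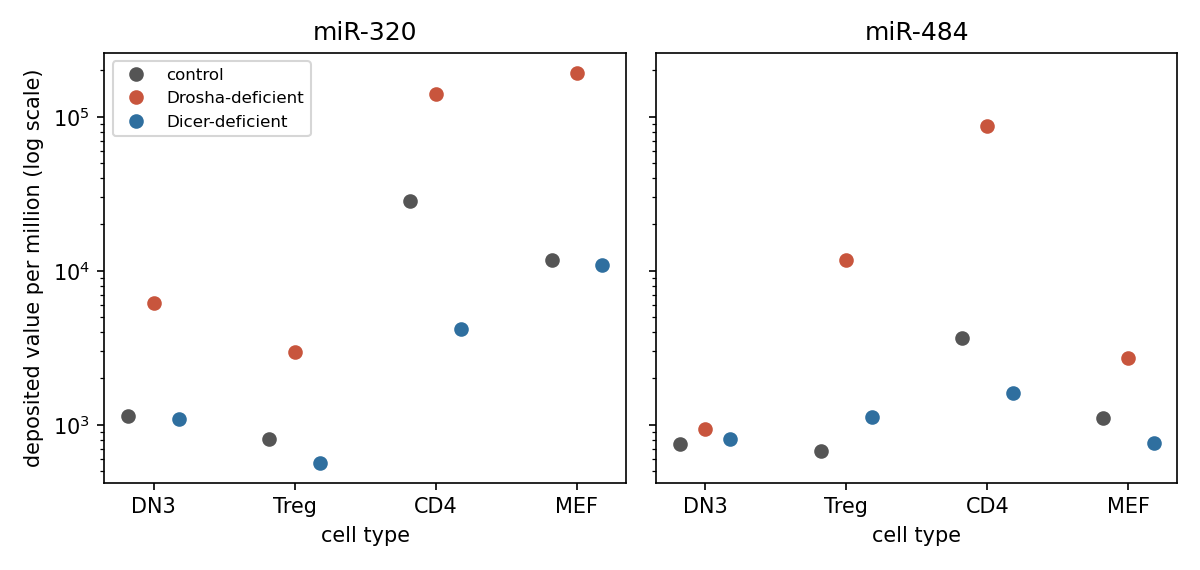
Deposited normalised values of miR-320 and miR-484 on a log axis for each cell type, with 1 point per library and colour for genotype. The Drosha point is the highest of the 3 in every cell type, from 2950 to 193941 for miR-320.

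miR-484, whose hairpin gene (chromosome 16, 14159626 to 14159692) overlaps a UTR of Marf1 on the opposite strand, was lower in Dicer than Drosha in 4 of 4 cell types. The difference was 10.4-fold in Treg, 54.0-fold in CD4, 3.56-fold in MEF and 1.16-fold in DN3, and its fitted change of -2.79 ± 0.81 had an adjusted p of 0.42; without CD4 it was -1.81. The next lowest p belonged to miR-125b-5p (2.26 ± 0.55), miR-7a (2.57 ± 0.87) and miR-362-3p (1.78 ± 0.53), all higher in Dicer. Of these only miR-7a was fitted in 4 cell types, miR-125b-5p in DN3 and MEF, and miR-362-3p in DN3 and Treg. Without the filter miR-125b-5p was at 1.37 ± 0.64. With floors in place of missing values miR-125b-5p was at 1.10 and miR-362-3p at 1.11, and miR-7a was at 1.53 without MEF. Adjusted over the list alone, both tested mirtron or short hairpin members passed, and both were lower. Of the members outside the fit, miR-877, in an intron of Abcf1 (chromosome 17, 35960730 to 35960814), was 428 in Treg Drosha and 18 in Treg Dicer. miR-702, overlapping a coding exon of Plod3 (chromosome 5, 136991433 to 136991541), was 168 and 30 in MEF.

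The entries derived from other non-coding RNA were lower in Dicer than Drosha by camera (median -1.11, adjusted p = 0.0034), with an adjusted p of 0.79 with an estimated correlation. Of the tested members only miR-720 and miR-805 were also fitted in DN3 and Treg. In MEF miR-689 was 6240 in Drosha and 67 in Dicer and miR-1937a 8630 and 989, and in Treg miR-720 was 2011 and 247 and miR-805 349 and 45. CD4 was mixed: miR-689 was 344342 and 269194 and miR-1937a 36974 and 57258, while miR-1983 (4605) and miR-1839-5p (2368) were listed in Drosha and not in Dicer. The myeloid list, miR-223, miR-125a, miR-24, miR-23a and miR-27a, had a median of 1.36 (adjusted p = 0.17), and the 8 other lists had adjusted p from 0.68 to 0.97. miR-451, which is cut by Argonaute in place of Dicer, was 7748 in Treg Drosha and 924 in Treg Dicer, and 4268 and 8341 in DN3. The lowest ratios by cell type were miR-320, miR-31, miR-351, miR-298 and miR-342-3p in DN3, miR-877, miR-484, miR-144, miR-451 and miR-720 in Treg, miR-484, miR-320, miR-1195, miR-715 and miR-181a in CD4, and miR-689, miR-320, miR-1839-5p, miR-1937b and miR-1274a in MEF. The highest were miR-149, miR-466b-3p, miR-15b*, miR-223 and miR-7a* in DN3, miR-338-3p, miR-362-3p, miR-466h, miR-297c and miR-15b* in Treg, miR-7a, miR-155, miR-21, miR-674 and miR-185 in CD4, and miR-7a, miR-27a*, miR-665, miR-149 and miR-92a in MEF, the last 5 over 2 to 4 reads in Drosha. The CD4 Drosha values of miR-7a and miR-674 were both 526, the lowest value of that library. Ratios at least 1 log2 unit from the median miRNA were found for 70 of 170 miRNAs in DN3, 27 of 173 in Treg, 21 of 71 in CD4 and 86 of 221 in MEF.

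The Dicer to Drosha ratios of different cell types, which share no library, were weakly related. Across miRNAs, which are not independent replicates, Pearson's r was 0.593 between Treg and CD4 (56 miRNAs), 0.401 between CD4 and MEF, 0.372 between Treg and MEF, 0.369 between DN3 and CD4, 0.352 between DN3 and MEF and 0.245 between DN3 and Treg (164 miRNAs). Spearman's rho ran from 0.285 to 0.343. Without the mirtron, slicer and non-coding RNA lists, r was 0.192 between Treg and MEF.

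In DN3 control cells, small RNAs inside genes were listed as 54267 distinct sequences over 10847 gene symbols. Introns held 25523 of them, the 5′ flank of transcripts 7841, coding exons 7228, 5′ UTRs 6935 and 3′ UTRs 2811. Sense sequences made up 72.6% (95% exact interval 72.2 to 73.0%). The interval treats the sequences as independent although many overlap, so it is too narrow. With 1 sequence per start position the share was 71.55%. The 5′ flank was the only class in which antisense sequences (4451) outnumbered sense ones (3390). Among the genes with most sequences were Gas5 (384) and Snhg1 (302), both hosts of small nucleolar RNAs, Eif4a2 (125), Malat1 (116), Hist1h1c (114), Tex14 (114), Nop56 (103), Gnl3 (87) and Trim7 (86). All but 1 of the Trim7 sequences were antisense. Sequence length peaked at 18 nt (8777), below the size range named in the labels, and 4296 were 22 nt long. These are numbers of distinct sequences, not of reads, and no deletion library had such a list here.

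**Figure D3:**
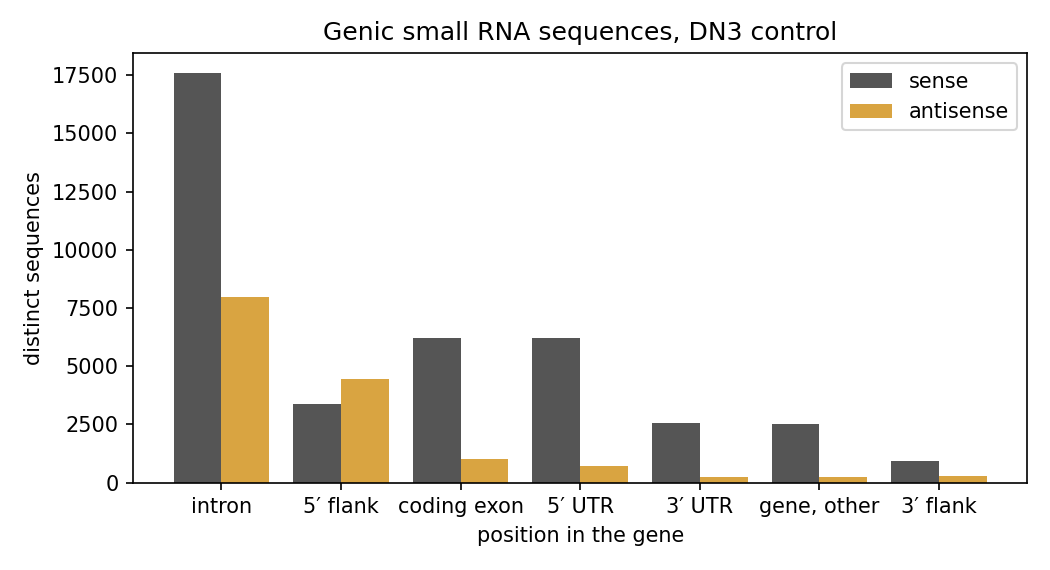
Bars give the number of distinct genic small RNA sequences in DN3 control cells by position in the gene, split into sense and antisense. Sense bars are the higher ones in each class except the 5′ flank, with 3390 sense and 4451 antisense sequences.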

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

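Of the tests in this part, those on strand pairs and on dilution were written down before their results were seen, and the others were chosen after them. miR-183 went in opposite directions in 2 cell types, a difference that was not tested because each value rests on 1 library per genotype. Relative to the median miRNA, its Drosha to control ratio was 3.50 in Treg (37 in control, 385 in Drosha) and -2.10 in MEF (218 and 26), and its Dicer to Drosha ratio was -2.10 in Treg and 2.29 in MEF. Both MEF ratios rest on about 2 reads in the Drosha library. Hairpin and loop sequences, which no comparison used, made up 0.605% of DN3 control, 0.411% of DN3 Drosha and 0.627% of DN3 Dicer, and 0.5625%, 0.437% and 0.387% of the Treg libraries in that order. In the DN3 control gene list, 584 sequences matched annotated miRNA hairpins exactly.

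miR-320 was lower in Dicer-deficient than in Drosha-deficient libraries. With median-of-ratios scaling the log2 difference was -3.73 ± 0.62. Both scalings are relative to the other miRNAs of a library. A loss of those miRNAs that differed between the 2 deletions could therefore not be excluded. The low depth of the CD4 deletion libraries does not account for the difference. Without CD4 it was -3.02 ± 0.48, close to -3.53 ± 0.55 with these libraries, although the call ended with fewer libraries (adjusted p = 0.064 in limma's test). A candidate explanation is a route that needs Dicer and not Drosha. Of the other entries of the mirtron or short hairpin list, 14 of 14 entries by cell type with a direction were higher in Drosha, some of them near the floor. This count does not single out the route in MEF and Treg. There, 10 of 11 and 2 of 2 entries derived from other non-coding RNA were also lower in Dicer, by at least 1 log2 unit relative to the median miRNA. In CD4 3 of 12 such entries were lower and 1 was higher, and in DN3 0 of 2 were lower or higher. Chance was not excluded for the number of calls, because 2 of the 35 splits of the 8 libraries, the real one included, gave as many (1 call in the real split, at most 1 in another). The other one parted the libraries of only 2 of the 4 cell types. Of the 8 splits that part every cell type, too few for a share under 5%, the real one gave 1 call and the highest other 0. Drosha against control and Dicer against control had 0 calls, which all 35 of 35 splits must reach, so the splits decide nothing there. The highest counts of other splits, 3 and 4, came from splits that part 2 cell types or 0.

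Erythroid and structural RNA entries were higher together in the Treg Drosha library, though not they alone: miR-181a (13227 in control, 59531 in Drosha) and miR-128 (935 and 4471), both among the 10 most abundant in DN3 control, were higher too. Lists with a large share in DN3 control did not rise as a whole. By at least 1 log2 unit relative to the median miRNA, 2 of 26 T lymphocyte entries were higher and 4 lower. In the miR-17~92 list 0 of 18 were higher and 2 lower. A smaller pool of the other miRNAs would turn, in per-million values, into a like shift of every entry outside that pool. Over the 7 members of the erythroid, slicer, mirtron and non-coding RNA lists compared in this library the log2 changes lay between 1.86 (miR-320) and 4.13 (miR-484), with an SD of 0.682, which does not decide for or against it. miR-877, not listed in control, stood 42.8-fold above the floor. RNA of red blood cells was not tested, because the tables do not show what else such RNA holds. The Drosha genotype itself stays open too, since no second Treg Drosha library was analysed here. The other Drosha libraries differed: neither miR-720 nor miR-805 was higher in DN3, while the list of entries from other non-coding RNA was higher, by at least 1 log2 unit relative to the median miRNA, in 13 of 14 members in CD4 and 12 of 12 in MEF. In CD4 this was not particular to Drosha, since 11 of 12 members were higher in the Dicer library too. Both CD4 counts are partly set by the floors, 20 in control, 526 in Drosha and 645 in Dicer. A member below the deletion floor in control could be compared only if it was higher, as with miR-1937b (40 in control) and miR-720 (30). In MEF Dicer 2 of 9 were higher.

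The passenger strand share was lower in the Drosha library than in control in all 4 cell types: 1.04 against 1.10% in DN3, 0.632 against 0.948% in Treg, 0.895 against 3.47% in CD4 and 0.757 against 1.81% in MEF. This was not particular to Drosha, since the share was also lower in the Dicer libraries of Treg (0.626%), CD4 (1.63%) and MEF (1.59%), though not of DN3 (1.35%). Without mirtron, short hairpin and structural RNA entries the starred strand share stayed lower in 4 of 4 cell types. Dilution by them is thus not the whole cause in Treg (0.646 against 0.955%) and MEF (0.938 against 1.83%). The DN3 difference was small (1.05 against 1.11%). CD4 tells little, because CD4 Drosha lists nothing below 526, against 20 in control, so low starred strands are missing there. Whether listing floors hide low passenger strands could not be decided. Over strand pairs listed in both libraries, the median passenger to guide change was below -0.2 in 2 of 4 cell types (-0.24 in DN3 and -1.06 in CD4, the latter from 2 pairs), and it was -0.04 in Treg and 0.10 in MEF.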

How the results depend on the processing

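Floors in place of missing values, a pseudocount of 10 and the set listed in all 12 libraries were chosen after the data were seen; the other settings were planned. The planned count-based tests of edgeR, DESeq2 and voom were not run, because the values are not counts. The 0 calls for Drosha against control became 7 among the 51 miRNAs listed in all 12 libraries and stayed at 0 in the other settings; those for Dicer against control stayed at 0 in every setting run. For Dicer against Drosha the 1 call became 5 with only the 2 genotypes (miR-320, miR-484 and miR-689 lower, miR-149 and miR-7a higher), 3 among the 51 miRNAs (miR-320, miR-484 and miR-7a), and 0 with floors in place of missing values, where miR-320 had an adjusted p of 0.077. Leaving out a cell type gave 0 to 2 calls: 0 without CD4 or MEF, 1 without DN3 and 2 without Treg. The cause was not tested. The 5 miRNAs with the lowest p of each comparison, miR-320 among them, kept their direction in the settings that tested them. Of the list tests, 4 passed with the preset correlation, and 0 with an estimated one. fry gave 0 in the 15 list tests it could be run on, which include only 1 of these 4, miR-17~92 for Dicer against control, with 4 of its 18 members.

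With a minimum of 200, fewer miRNAs are counted, except in CD4. The number at least 1 log2 unit from the median then was 42 in DN3 and 33 in Treg for Drosha against control, 6 in DN3, 12 in Treg and 2 in MEF for Dicer against control, and 17 in Treg for Dicer against Drosha. Relative to the library total it was 128 in MEF for Drosha against control and 38 in CD4 for Dicer against Drosha. That scaling turned the balance of higher to lower from 28 and 37 to 9 and 53 in DN3 Drosha, from 32 and 21 to 28 and 41 in CD4 Drosha, and from 6 and 4 to 1 and 10 in MEF Dicer. For Dicer against Drosha it turned 38 and 32 into 54 and 15 in DN3, 9 and 12 into 33 and 5 in CD4, and 43 and 43 into 90 and 26 in MEF. The correlation of Treg and MEF ratios was 0.192 without the noncanonical lists. Without the most abundant miRNA of each control the T lymphocyte share was 39.0% in DN3, 66.9% in Treg, 19.95% in CD4 and 6.87% in MEF, and the fibroblast share 0.735%, 2.15%, 0.291% and 38.2%. The sense share of genic sequences was 74.9% for 20 to 24 nt and 71.55% with 1 sequence per start position. The low depth of the CD4 deletion libraries limits what can be listed there. Their lowest values, 526 in Drosha and 645 in Dicer, lie above the minimum of 200. That setting therefore left the CD4 numbers against control at 53 for Drosha and 67 for Dicer and could not check them.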

Other observations

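Some genic sequences of DN3 control cells matched annotated miRNA hairpins. Dgcr8, the partner of Drosha, held 51 sequences, of which 19 matched the Mir1306 hairpin in its coding sequence (chromosome 16, 18284340 to 18284402 in the build of the list) and 15 matched Gm24572, annotated as a miRNA gene, in its 5′ UTR (18284655 to 18284716). Other hairpins with many matches were mmu-mir-3535 in an intron of Ncl (33 sequences), Mir3068 in an intron of Alkbh1 (29) and Snord43 in an intron of Rpl3 (28), which the annotation types as miRNA genes. In all, 172 hairpins were matched, and 438 of the 584 matching sequences were 20 to 24 nt long, against 39.4% of all genic sequences. These genes were chosen after their values were seen.

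The miR-183, miR-182 and miR-96 cluster, known in activated T cells, had higher values in Treg Drosha (385, 652 and 362) than in Treg control (37, 138 and 64), while Treg Dicer stood at 89, 216 and 116. In CD4 Dicer the values were 968, 1290 and 645 against 360, 1070 and 200 in control, but these Dicer values rest on about 6, 8 and 4 reads. In MEF they were lower in Drosha (26, 90 and 26) than in control (218, 389 and 73), the Drosha values resting on about 2, 7 and 2 reads. miR-223, a myeloid miRNA, was high in both Treg deletion libraries, 588 in Drosha and 746 in Dicer against 24 in control, whereas miR-23a was 8695, 13426 and 10067 there.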
